A study of Humulus lupulus with 12 samples.

How the data were processed

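Total RNA was isolated from fully expanded hop leaves with a plant RNA column kit, and libraries were made with Illumina protocols, per the labels' protocols. Plants grew at 25 to 28 °C with 14 h of light and 10 h of darkness. Infected plants had received an extract of a viroid-infected hop plant, and collected leaves were inoculated with mildew at 20000 spores per mL. The labels do not say whether the replicates of a group came from separate plants, so p-values measure the spread between these samples, which may be technical. No label gives a time after inoculation or a mock inoculation.

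The deposited table held read counts per feature, made from trimmed reads, per the file headers. The counts used were the total gene reads, which per the file headers stand beside a separate column of unique reads, so reads that match several features are included. The mapper, its settings and the reference are not given in the sources used here. The reference had 387927 features with identifiers and lengths. Features that share sequence (copies, alleles or fragments of a gene) can share reads, so counts of features are not counts of genes. Consecutive identifiers changed alike: over 41302 pairs of neighbouring tested features, the log2 fold changes of HPM against control correlated at 0.67, against -0.01 for random pairs. The RefSeq gene table of the hop assembly drHumLupu1.1 matched 0 identifiers. The 33 gene lists fixed before the data were examined, their tests and the annotation term enrichment were therefore not run.

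The columns name the group and a library number but no replicate number, so libraries were assigned to groups only. The authors' table held 59 further columns of per-library or per-group values (unique reads, RPKM, normalized values and means), which were not used here. RPKM for an alternative analysis were computed from the deposited counts and feature lengths.

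All 12 libraries entered a single fit with 1 coefficient per group, in edgeR 4.0.16 (R 4.3.3), with TMM scaling, filterByExpr by group and robust quasi-likelihood dispersions; 75522 features passed the filter. Features past a Benjamini-Hochberg FDR of 0.05 were called. There were 5 comparisons between groups and the interaction, (mixed minus HPM) minus (HSVd minus control). An average mildew effect over both viroid states was added after the data were seen. TMM factors averaged 0.776 in control, 0.958 in HSVd, 1.34 in HPM and 1.05 in mixed libraries, with 0.562 in X1. CPM values use the TMM-scaled library size. A fold against a group at 0 reads was computed against 3 reads over the group and is a lower bound. Counting intervals are exact 95% Poisson intervals of the lower group's reads, and intervals and floors cover counting error only. At 3 reads per library the floor lay between 0.179 and 0.330 CPM.

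The rule for features named in the text was fixed before the data were examined: the largest changes among called features with non-overlapping groups and a mean of at least 5 CPM in the higher group. The rule also asked for a gene description, and the table gives none, so that condition was dropped and the largest rise and fall of the HSVd and HPM comparisons were kept.

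Alternatives fixed before the data were examined were no scaling beyond library size, upper quartile scaling, no filter, a filter of 1 CPM in at least 3 libraries, only the 2 groups compared, limma 3.58.1 on log2(RPKM + 0.1) and log2(RPKM + 1) for 99569 features above 0.5 RPKM in at least 3 libraries, a minimum of a 2-fold change, DESeq2 1.42.0, and leaving out each library. Alternatives chosen after the data were seen were thinning every library to the 10157773 reads of the shallowest, thinning every library to the lowest TMM-scaled size (9102013 reads in X1), leaving out the features on in HPM leaves only, and counting runs of consecutive identifiers as 1. DESeq2 gave no adjusted p for 91 features in each comparison, and these were left out of its counts.

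Before averaging, replicates were compared by a chi-square of their counts. The lowest value per degree of freedom within a group was 4.91, so no pair of libraries differed by as little as sampling noise. The fit was tested on simulated data made from the real means, dispersions and library sizes, with 200 features changed. In the simulated HPM comparison, with 70061 features run, 60.9% of the 8-fold, 12.6% of the 4-fold and 0 of the 2-fold changes were called, with 3 false calls. In the simulated HSVd comparison of 69685 features these shares were 61.4%, 27.7% and 0. In the simulated interaction of 69044 features they were 13.3% of the 8-fold and 0 of the smaller changes. Figures were drawn with matplotlib.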

Results

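Hop leaves infected with a viroid, a fungus or both were profiled by RNA sequencing. The plants were *Humulus lupulus*, cultivar Willamette. Hop stunt viroid (HSVd) is a small circular RNA that encodes no protein and replicates in the host nucleus. Hop powdery mildew (HPM) is caused by *Podosphaera macularis*, a fungus that feeds on living epidermal cells of the leaf. There were 4 groups of 3 libraries: untreated leaves (control), leaves of viroid-inoculated plants (HSVd), healthy leaves inoculated with mildew spores (HPM), and viroid-infected leaves inoculated with mildew spores (HSVd-HPM, here the mixed group). Libraries are named by the numbers in the column headings: X1 to X3 control, X4 to X6 HSVd, X7 to X9 HPM, and X10 to X12 mixed.

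The total per library was 10157773 to 16426070 reads. Group means were 14706251 ± 1494904 reads (SD, n = 3) in control, 13656944 ± 2116220 in HSVd, 11749410 ± 2587050 in HPM and 12143119 ± 812484 in mixed leaves. Reads fell on 251148 of the 387927 reference features, and 75522 features had enough reads to be tested. The features carry identifiers and lengths only. The files do not pair the identifiers with genes, so the changes are described as groups of features, and 4 identifiers are given as examples.

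Mildew-inoculated leaves stood further from control leaves than viroid-infected leaves did. The first principal component held 51.8% of the variance. Its mean score was -154.6 in control, -115.2 in HSVd, 68.7 in mixed and 201.1 in HPM leaves, and the ranges of the groups did not overlap except between control (-177.2 to -121.5) and HSVd (-139.8 to -78.0). The median rank correlation of a control with an HSVd library was 0.81, across features, against 0.84 between control libraries and 0.878 between HSVd libraries. Control and HPM libraries correlated at 0.473, control and mixed libraries at 0.603, and HPM and mixed libraries at 0.688. These correlations are across features, which are not independent replicates.

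**Figure D1:**
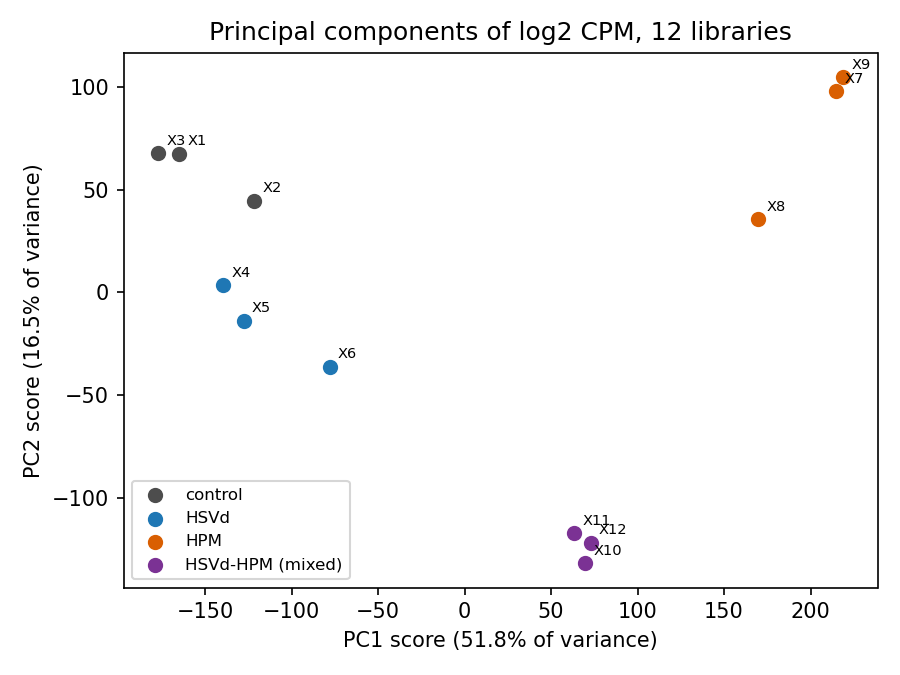
Scores of the 12 libraries on the first and second principal components of log2 CPM (51.8% and 16.5% of the variance), with 1 point per library coloured by group. HPM and mixed libraries lie at positive scores of the first component, and control and HSVd libraries at negative scores.

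Few transcripts supplied a large part of the RNA in every group. The most abundant feature, 7546 bases long, took 16.7% ± 2.15 (SD, n = 3) of reads in control leaves, 21.7% ± 2.53 in HSVd, 11.4% ± 1.25 in HPM and 26.3% ± 2.22 in mixed leaves. The shares of the groups compared did not overlap in any of the 5 comparisons. The closest were HSVd and mixed leaves, with 24.6% in X6 and 24.7% in X11. Each of the 5 pairwise comparisons of groups gave p = 0.1 in a two-sided exact permutation test (0.1 after Benjamini-Hochberg adjustment), which is the smallest p that 3 against 3 libraries allow. The 20 most abundant features together took 57.5% ± 7.58 of reads in control, 49.7% ± 2.55 in HSVd, 33.5% ± 4.60 in HPM and 54.0% ± 4.92 in mixed leaves.

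The comparison of HSVd with control leaves asks what the viroid changes on its own. Viroid infection changed 1336 of 75522 features, of which 818 were higher and 518 lower. The changes were large where they were called, with a median log2 fold change of 2.62 for the higher and -2.96 for the lower features (2.59 and -2.91 with features at 0 reads in a group set to their bound). At least 8-fold changes were found in 334 features that rose and 247 that fell. The called features held 1.89% of all reads. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 11824 features had an unadjusted p under 0.05, and 18.6% of all features had HSVd and control values that did not overlap, against 10% by chance.

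The largest rise in HSVd leaves was LA361250, a feature of 1668 bases. It had 322 ± 341 CPM (SD, n = 3; 28 to 7407 reads per library) in HSVd leaves and 2 reads over the 3 control libraries, a ratio of 5074 (95% counting interval 1405 to 41898; log2 fold change 12.17, SE 2.39). Its adjusted p was 0.0227 in edgeR's quasi-likelihood test, and it was higher in 3 of 3 HSVd libraries, although X4 had only 2.31 CPM. It was also higher in HPM leaves (15.3 ± 19.8 CPM; edgeR adjusted p = 0.016) and had 0.201 ± 0.290 CPM in mixed leaves. The call in HSVd leaves was lost in 7 alternative analyses, with an adjusted p of up to 0.115, and the fitted log2 fold change was 11 without X6. The largest fall was LA484695, of 2601 bases. Control leaves had 45.0 ± 27.9 CPM and all 6 viroid-inoculated libraries had 0 reads, at least a 597-fold fall in HSVd leaves against a floor of 3 reads over the group (edgeR adjusted p = 0.0015). It also fell in HPM leaves, to 0.706 ± 0.180 CPM, by a ratio of 65.8 (95% counting interval 46.6 to 96.1; edgeR adjusted p = 0.000206).

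The HSVd count depended on individual libraries: 463 features were called without X1, 573 without X5 and 517 without X6. It was 2869 with DESeq2, 5410 with no filter on low counts and 371 when only these 2 groups were fitted; of the calls, 79.2% were higher with no scaling beyond library size, against 61.2%. Without X1 the balance turned, with 217 higher and 246 lower (46.9% higher), and without X2 it was 52.3%.

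The comparison of HPM with control leaves asks what mildew changes in viroid-free leaves. Mildew-inoculated leaves differed from control leaves in 26716 features, 35.4% of those tested, with 13459 higher and 13257 lower. These features held 74.3% of all reads. The median log2 fold change was 2.2 for the higher and -2.14 for the lower features, and 4530 rose and 3670 fell by at least 8-fold. The labels describe the control leaves as untreated, so inoculation and the handling of collected leaves differ together with mildew in this comparison. Of the 26716 features, 2066 had 0 reads in control or in HPM leaves. The features were not traced to an organism, so those higher in inoculated leaves need not all be leaf transcripts, here and in the other comparisons with inoculated leaves.

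The largest rise was LA328176, a feature of 626 bases, with 598 ± 340 CPM (SD, n = 3; 3797 to 15491 reads per library) in HPM leaves and 0 reads in control leaves. This was at least a 6696-fold rise (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.82e-05), seen in 3 of 3 HPM libraries. The same feature had 3 reads over the HSVd libraries and 2 over the mixed libraries. The largest fall was LA553185, of 2161 bases, with 167 ± 174 CPM in control leaves, 120 ± 108 in HSVd leaves and 0 reads in HPM leaves. This was at least a 2407-fold fall (edgeR adjusted p = 0.000362), and mixed leaves had 1 read. Control X3 held 368 CPM, against 51.5 in X1 and 82.1 in X2, and without X3 the fitted log2 fold change moved from -14.07 to -12.78 (edgeR adjusted p = 0.000681).

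The direction of the HPM changes depended on the scaling. Without scaling beyond library size, 80.8% of 32288 calls were higher, against 50.4% of the calls reported above, and the median of all features shifted by 0.807 on the log2 scale; the 2 limma fits on log2 RPKM gave 82.2% and 83.1% higher.

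**Figure D2:**
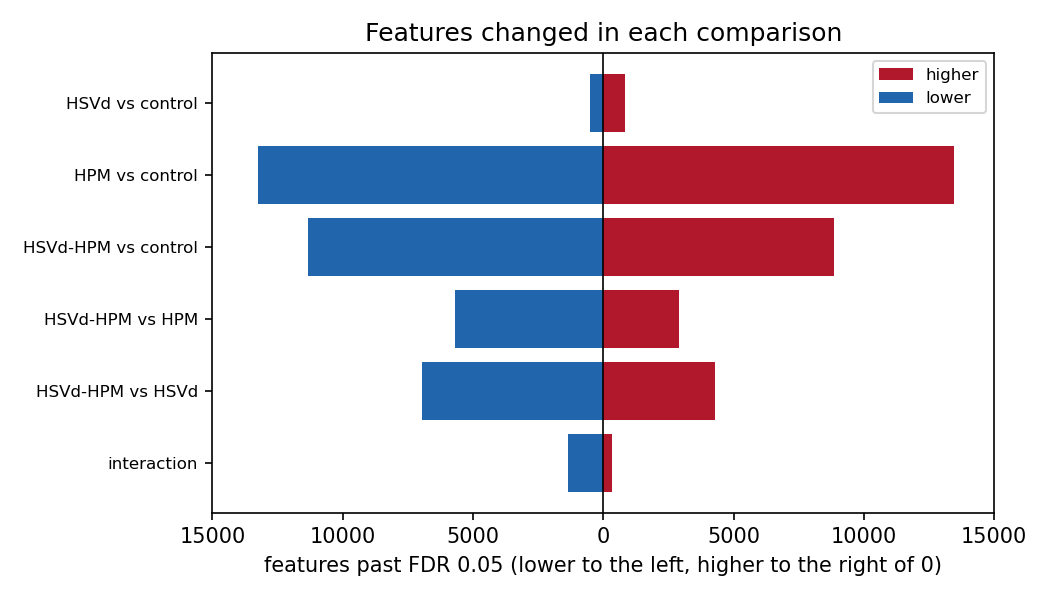
Number of features past an FDR of 0.05 in each comparison, with higher features to the right and lower features to the left of 0. The bars reach 13459 higher and 13257 lower in HPM against control leaves, and 818 and 518 in HSVd against control leaves.

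The comparison of mixed with control leaves asks what infection by viroid and mildew together changes. Mixed leaves differed from control leaves in 20186 features, 8853 higher and 11333 lower, with median log2 fold changes of 1.97 and -2.09. Inoculation and handling differ together with viroid and mildew in this comparison. At least 8-fold changes were found in 2010 features that rose and 3002 that fell. Without scaling beyond library size 67.2% of calls were higher, against 43.9%, with a median shift of 0.424, and the limma fits gave 70.3% and 68.8%.

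The comparison of mixed with HPM leaves asks what the viroid changes in leaves that also carry mildew. Here 8583 features differed, with 2891 higher and 5692 lower in mixed leaves. Of the 8583, 1522 had 0 reads in HPM or in mixed leaves. Leaving out the 280 features on in HPM leaves only, described below, gave 8214 calls, 5372 of them lower. The 280 reached 5 CPM in every HPM library, so features read in HPM leaves only with fewer reads stayed among these calls. The features were not traced to an organism, so the lower ones need not all be a response of the leaf to the viroid. The median log2 fold change was 2.07 for the higher and -2.8 for the lower features, and 724 were at least 8-fold higher and 2670 at least 8-fold lower. LA328176, which HPM leaves held at 598 CPM, was lower by a ratio of 11361 (95% counting interval 3145 to 93811; edgeR adjusted p = 8.33e-05). The count was 4996 without X7, 4857 without X10, 5708 without X11 and 13812 with no filter on low counts. The share of higher calls was 33.7%, against 15.2% with no scaling beyond library size (median shift -0.358), 19.3% and 17.2% in the limma fits, and 47.4% with upper quartile scaling (median shift 0.179).

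The comparison of mixed with HSVd leaves asks what mildew changes in viroid-infected leaves. Mixed leaves differed from HSVd leaves in 11249 features, 4282 higher and 6967 lower, with median log2 fold changes of 1.99 and -2.22. No label gives a mock inoculation of HSVd leaves, so inoculation and handling differ together with mildew here too. LA553185 fell again, from 120 CPM to 1 read over the group, a ratio of 4944 (95% counting interval 887 to 195297; edgeR adjusted p = 0.00179). LA361250 also fell, by a ratio of 1435 (95% counting interval 728 to 3324; edgeR adjusted p = 0.00598). The count was 6592 without X5, 6307 without X10 and 7415 without X11, and the limma fits called 6619 and 6895.

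Many features moved in the same direction with mildew inoculation whether or not the viroid was present. Mildew and the handling that goes with inoculation cannot be told apart in this agreement. HPM against control and mixed against HSVd share no library, and their log2 fold changes correlated at r = 0.59 across features. Both comparisons called 8380 features, of which 2949 rose in both (763 expected for independent lists) and 5263 fell in both (1223 expected), while 168 went opposite ways. Of the features called in viroid-infected leaves, 92.6% had the same sign in viroid-free leaves. Of those called in viroid-free leaves, 82.9% had the same sign in viroid-infected leaves and 31.4% were called there. The viroid's changes with and without mildew also share no library, and correlated at r = 0.17. Both viroid comparisons called 678 features, 321 higher in both (31.3 expected), 265 lower in both (39.0 expected) and 92 opposite. Of the features called for the viroid without mildew, 75.3% had the same sign with mildew, and of those called with mildew 50.04% had the same sign without it. Features without reads in both groups of a comparison have no sign there, yet they remain in all of these shares. An example is LA328043, with fitted log2 changes of 0 without and -7.87 with mildew. The median change without mildew of the features called with it was 0, so 50.04% partly reflects features that could not be measured. Features are not independent replicates.

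HSVd and HPM each changed some of the same features relative to control. Both called 686 features, with 425 higher in both (146 expected for independent lists), 189 lower in both (90.9 expected) and 72 opposite. The simulated unchanged groups had no calls at all, so they give no overlap to set beside this count. The log2 fold changes correlated at r = 0.29, and simulated unchanged groups against the same controls gave 0.52. Their covariance was 0.68, against 0.15 in simulation, a difference of 0.53. With 3 control libraries the controls cannot be split, so part of the excess overlap may come from them.

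The interaction asks whether the viroid's change differs with and without mildew, or equally whether the mildew's change differs with and without the viroid. It was called in 1671 features, 330 positive and 1341 negative. Features without reads in several groups could hardly be called. LA329384, with log2 changes against control of 11.98 in HPM leaves and 0 in HSVd and mixed leaves, had an interaction of -11.98 that was not called. LA484695, at 0 reads in HSVd and mixed leaves, had an SE of 14171 and was not called. The 1671 features are therefore not all those whose change may differ. Of the 1341 negative features, 1192 rose with mildew in viroid-free leaves, and 75 of these also rose in viroid-infected leaves. The median log2 mildew change of the negative features was 2.69 in viroid-free and -0.46 in viroid-infected leaves. Of the 330 positive features, 299 fell with mildew in viroid-free leaves, with medians of -2.61 without and 0.08 with the viroid. The sign of the interaction fixes which of the 2 mildew changes is lower. These counts and medians therefore describe the called features and are no further evidence. The fitted interaction of LA328176 was -16.36 (log2, SE 2.78, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0164). Both the value and the call rest on 0 reads in control, 3 in HSVd and 2 in mixed leaves, so the value is no measure of size. That of LA361250 was -18.28 (SE 3.05; edgeR adjusted p = 0.0125), with 2 reads in control and 8 in mixed leaves. The count was 284 without X10, 339 without X7, 485 without X11, 654 without X1, 723 without X6, 763 without X9, 903 without X5 and 2610 without X8. It was 4095 with DESeq2, 5401 with no filter on low counts, and 3463 with no scaling beyond library size, where 2.57% of calls were positive against 19.7%; the median shift was -0.649, and the limma fits gave 5624 and 7013 calls.

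Some features were on in whole groups and off in others. A feature was taken as on at 5 CPM or more in every library of a group and as off at 3 reads or fewer in every library. In HPM leaves alone, 280 features were on, with a median of 22.2 CPM. They took 1.33% ± 0.647 of reads (SD, n = 3) in HPM leaves and no more than 0.000513% in any mixed library, 132 reads against 492543. Mildew-inoculated leaves of both kinds shared 13 features that were off in control and HSVd leaves, and 28 features were on in control and HSVd leaves and off in both inoculated groups. Another 2 were on in both viroid-free groups only. No feature was on only in control, only in HSVd, only in mixed, or only in the 2 viroid groups; leaving control X3 aside, 6 were on in the 2 viroid groups only, and X3 was on in 4 of these.

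**Figure D3:**
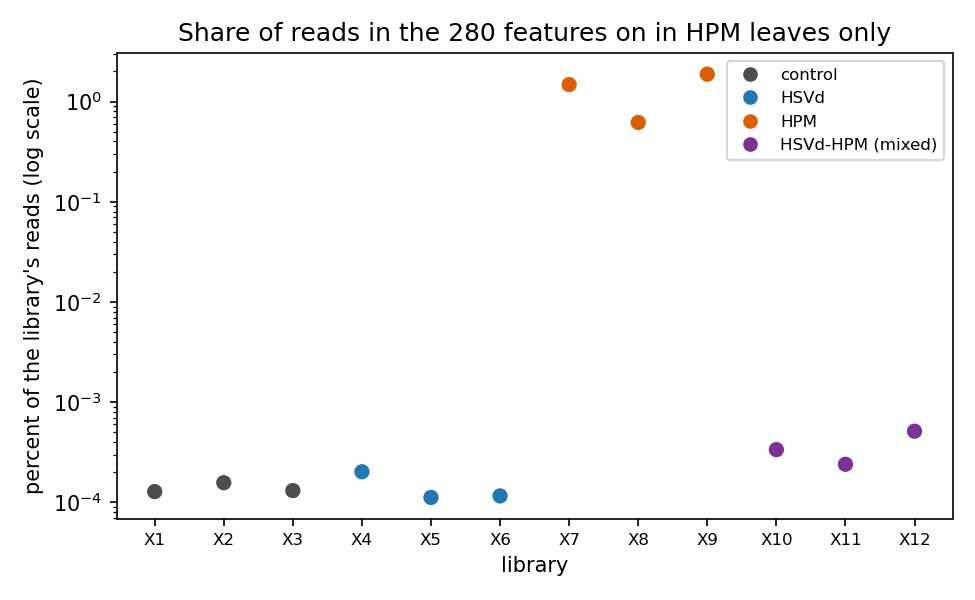
Percent of each library's reads, on a log scale, in the 280 features that were on in HPM leaves only, with 1 point per library. The HPM libraries lie between 0.619% and 1.88%, and the other 9 libraries at or below 0.000513%.

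Some libraries stood apart from their groups. For each library, features were taken that separated the other 11 libraries by at least 4-fold into those with and without viroid, and the library was placed between them, at 0 with the viroid-free and at 1 with the viroid libraries. Control X3 fell on the viroid side in 53 of 93 features. HSVd X4 did so in 30 of 46 and mixed X12 in 34 of 39, and the other libraries lay on the side of their label in all of their 30 to 34 features. On the matching mildew axis, HSVd X6 had a median position of 0.25 and fell on the mildew side in 132 of 794 features, while the other uninoculated libraries did so in 2.61% or less. Without X3 the HSVd comparison called 1763 features, and without X6 it called 517.

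**Figure D4:**
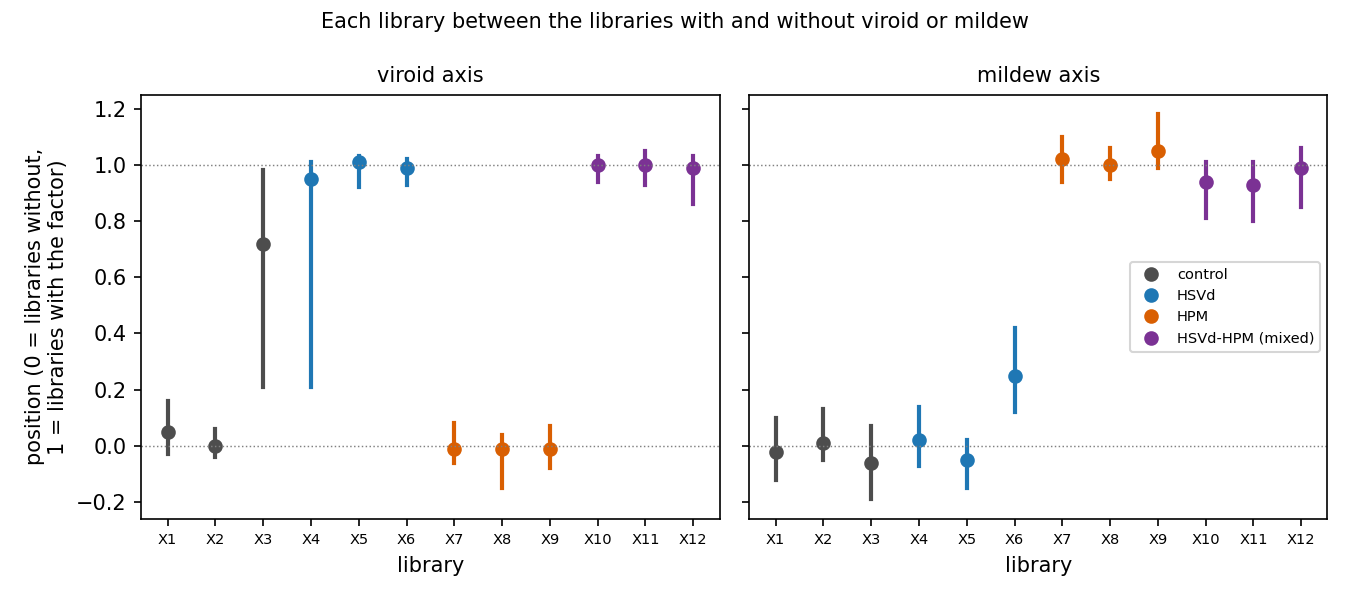
Position of each library between the libraries without (0) and with (1) viroid or mildew, over features that separated the other 11 libraries by at least 4-fold; points are medians and lines the interquartile range over features. Control X3 has a median of 0.72 on the viroid axis, and HSVd X6 one of 0.25 on the mildew axis.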

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

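The average mildew effect with its splits, and the tests of the choice of features, of depth, of single libraries and of the features on in HPM leaves only, were chosen after the results were seen; the 5 comparisons, the interaction and their splits were planned. A test of the difference itself flagged 3 results: the interaction count of 1671 features, and the interactions of LA361250 (-18.28) and LA328176 (-16.36). The size of the last is not measured, since control had 0 reads of it.

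For the interaction, 24 redraws of the viroid labels within each mildew state were sampled at random from those possible. With the real one, 1 of 25 splits reached 1671 features, the smallest share this sample allows and under 0.05. Such redraws put viroid and viroid-free libraries in 1 group. They ask whether the viroid has any effect, not whether its effect differs with mildew, so they cannot exclude chance for the count of 1671. The highest of the other splits called 318 features, more than the 284 that the real split called without X10. In the split with 318 calls, control X3 and HSVd X4 had changed places. A like sample of the mildew labels within each viroid state also made 25 splits with the real one, of which 1 reached the 28249 features called for the average mildew effect, and the highest other called 98. Those redraws put inoculated and uninoculated libraries in 1 group, which adds the mildew difference to the spread and lowers the calls. For the 5 comparisons of 3 against 3 libraries, 10 splits exist, too few for a share under 0.05. Their other splits mix the groups compared in the same way, so low counts in them are weak evidence against chance. The real splits called 1336 (HSVd against control), 26716 (HPM against control), 20186 (mixed against control), 8583 (mixed against HPM) and 11249 features (mixed against HSVd), and the highest other split called 0 in each; 1 of 10 splits reached the real count.

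The interaction of LA361250 rests on 28 to 7407 reads in the HSVd libraries, 4 to 578 in the HPM libraries, 0 to 1 in control and 0 to 7 in mixed libraries. Its mean was higher with either agent alone than in control or mixed leaves, but the libraries were uneven. HPM X9 had 0.239 CPM, below the 0.533 of mixed X11, while HPM X8 had 37.7. HSVd X4 had 2.31 CPM and HSVd X6 681.

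With TMM scaling, the mildew effect was smaller in viroid-infected than in viroid-free leaves. It was not measured with another scaling. The median interaction over all features did depend on the scaling. It was 0.007 with TMM, -0.649 with no scaling beyond library size and 0.163 with upper quartile scaling. Over 28249 features called for the average mildew effect, the median log2 change in the direction of the average was 1.86 in viroid-free and 1.20 in viroid-infected leaves, a median difference of -0.62 (-0.61 with features at 0 reads set to their bound); over the 11249 features called in viroid-infected leaves, a choice that leans to that arm, the medians were 2.14 and 2.12. The choice by the average leans to the noisier viroid-free arm (median SD of log2 CPM 0.412 in control and 0.291 in HPM, against 0.322 in HSVd and 0.279 in mixed libraries), but this is not the whole cause: in libraries held out of the choice, 1 per group in each of 3 sets, the difference was -0.44, -0.33 and -0.8, with a mean of -0.52. Library depth and the 280 features on in HPM leaves only are not the whole cause. The difference was -0.62 with libraries thinned to the same total, -0.65 with libraries thinned to about the same TMM-scaled size, and -0.61 without those features. Features read in HPM leaves only but under 5 CPM in a library stayed in, so their part was not tested. HSVd X6, which lay partly toward the inoculated libraries, is not the whole cause either, since the difference was -0.51 without X6 (-0.88 without X2). The effect of the viroid itself, which the design names, remains open and untested here, as no label or value measures mildew on the leaves.

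LA328176 belongs to the 280 features on in HPM leaves only. RNA of the inoculated mildew carried alike by both inoculated groups is argued against by features on in every HPM and off in every uninoculated library, chosen without looking at the mixed libraries: of 347, 280 were off in all mixed libraries, and the highest share of reads in a mixed library was 4.64% of that in the lowest HPM library. RNA of 1 source apart from the leaf remains open: the 280 features varied together between HPM libraries, with a median log2 ratio of X9 to X8 of 1.88 and a median absolute deviation of 0.32. None of 10000 random lists of other risen features, matched on abundance, was as high (0.19 to 0.47) or as tight (0.41 to 0.75), and the 280 crowd in identifier order: of 40 equal ranges of identifiers the first held 68 and the last 113, while no range held more than 31 features of any random list. Mildew that grew on the HPM leaves only, another organism on those leaves, or a block of leaf genes switched on together could each give this, since the sources do not say what the order of the identifiers follows. The random lists were matched on abundance and not on identifier order. Neighbouring features changed alike in general, so the lists do not show how tight a crowded set would be by itself.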

How the results depend on the processing

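The thinned (to the same total or the same scaled size), HPM-only and run-counting alternatives were chosen after the data were seen; the others were planned. Mixed against control stayed within 1.5 times of 20186 in all alternatives run (13876 to 21390 leaving out libraries), and HPM against control of 26716 in all but the count of runs of consecutive identifiers (17475, fewer by construction; 21443 to 28521 leaving out libraries). HSVd against control moved from 1336 to 5410 with no filter on low counts, 371 with only the 2 groups fitted and 2869 with DESeq2, and ranged from 463 (without X1) to 1763 (without X3). Mixed against HPM moved from 8583 to 13812 with no filter, and from 4857 (without X10) to 10443. Mixed against HSVd moved from 11249 to 6619 and 6895 with limma (pseudocounts 0.1 and 1), and from 6307 (without X10) to 12295. The interaction moved from 1671 to 3463 with no scaling, 5401 with no filter, 5624 and 7013 with limma and 4095 with DESeq2, and from 284 (without X10) to 2610 (without X8). The cause of these moves was not tested. Leaving out a library leaves a group of 2. The correlation of HSVd and HPM fold changes was 0.29 to 0.42 leaving out controls (0.42 without X2) and 0.36 at 5 CPM or more.

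LA361250 kept its direction and lost its call in 7 alternatives: no filter (adjusted p = 0.115), both limma fits (0.0542 and 0.109), and without X1 (0.103), X2 (0.0674), X3 (0.0593) or X6 (0.0618). LA484695, LA328176 and LA553185 kept direction and call in all alternatives that tested them. No paired analysis was possible because the columns carry no replicate numbers. The unique-read alternative and the gene list tests were not run. In simulation, with 200 changed features, no 2-fold change passed the threshold. The simulated HPM comparison had 43 calls against 26716 in the real one, so its adjusted threshold was stricter and the 2 cannot be set side by side. Of the 26716 calls in HPM leaves, 25150 were at least 2-fold.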

Other observations

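The tests of explanations in this part were chosen after the results were seen.

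Features read in all 6 inoculated libraries at 1 CPM or more and off in the 6 uninoculated ones numbered 83. They took 0.262% ± 0.0684 of reads (SD, n = 3) in HPM leaves and 0.0515% ± 0.0136 in mixed leaves, with a median log2 difference of -0.80 (interquartile range -1.79 to -0.06); 63 were lower and 20 higher in mixed leaves.

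Features that separate viroid from viroid-free libraries did not follow the labels in control X3, which lay on the viroid side in 53 of 93. An exchange of control X3 with HSVd X4 is argued against: of 118 features separating the other 10 libraries, 0 put X3 on the viroid side and X4 on the viroid-free side, while X4 lay on the viroid side in 102. All-or-none differences between plants are a candidate explanation, since X3 lay at either end (within 0.3 of the distance) in 86.0% of the features, but this was the lowest share on the viroid axis (87.2% to 100% in the other 11 libraries, and 59.9% for the graded shift of HSVd X6 on the mildew axis), with a median position of 0.72 and a lower quartile of 0.21. A response to the viroid alone cannot be told apart from plant differences for the 53 features, because a wrong label of X3 alone would need no partner. X3 lay on the viroid side in 57.0% of features. This is between the 0% of X1, X2, X7, X8 and X9 and the 87.2% to 100% of 5 viroid libraries. The features of those libraries were chosen with X3 counted as viroid-free, so these shares cannot decide its label. The 65.2% of HSVd X4 was nearer to that of X3, but was taken over other features. Over the 118 features chosen without X3 and X4, X3 lay on the viroid side in 57 (48.3%) and X4 in 102 (86.4%). Beside X4, the last values go against a wrong label of X3 but do not exclude it. X3 did not lie with the other viroid-free libraries either, so its state stays open.

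Leaving X3 aside, 9 features were on in viroid-free leaves and off in the 6 viroid libraries, and X3 was off in 6 and on in 2 of them. In the other direction 6 features were on in the 6 viroid libraries and off in the other viroid-free ones, and X3 was on in 4 and between the limits in 2.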
